A study of Mus musculus with 24 samples.

How the data were processed

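The samples were RNA-seq libraries of mouse bone marrow cells. Per the labels, marrow of female mice aged 10 to 12 weeks was expanded for 72 hours with 40 ng/mL mCSF, plated at 25000 cells per well and given 10 ng/mL RANKL with 20 ng/mL mCSF, and RNA was taken from pooled wells at days 0, 2, 3 and 4. The replicate is the mouse: 3 WT and 3 STING-deficient mice each gave 1 library per day. P-values rest on the spread between libraries of different mice within groups, pooled over the days. The fit described below has no term for the mouse, so libraries of 1 mouse from different days count as independent.

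Per the submitters' processing notes, the authors aligned reads to mm10 and used HISAT2 2.0.5, Cufflinks 2.2.1 and Cuffdiff. The deposited values are FPKM per gene and library, 1 table for the whole series, and fragments per gene were not used here. Trimming, strandedness, annotation and multi-mapping rules are not given in the sources used here. The table holds 10721 genes, its name marks them as selected, and the rule for that selection is not given, so every adjusted p below is adjusted over a preselected set, and interferon genes such as Ifnb1 were not analysed here. All 24 value columns carried the genotype, day and mouse of 1 sample each, and 0 were left unused.

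Because FPKM are not counts, no count model was used. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, which fits 1 mean per group of genotype and day and 1 spread per gene with a mean-variance trend (16 residual degrees of freedom). Genes with a group mean of at least 1 FPKM in at least 1 group were kept, 10081 in all. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, at 0.05. The 11 comparisons were KO against WT at each day, each RANKL day against day 0 within each genotype, and the genotype by day interaction. The design, the alternatives, the rule for named genes and 25 gene lists were fixed before the data were examined; 23 lists held at least 3 tested genes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 23 lists, and again with an estimated correlation. List members were matched by symbol or by a RefSeq synonym, and 89.5% of the table's symbols are current RefSeq symbols.

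The text names Sting1; in the genotype comparisons, the interaction and day 4 against day 0, the 8 largest rises and 8 largest falls among genes past the threshold with at least 1 FPKM in the higher group and no overlap between the groups' samples; the 4 interferon-stimulated and 4 osteoclast effector genes with the smallest adjusted p; and the 3 such members of every other list that passed. Unnamed gene models are outside the rule. Genes named outside it are said to have been chosen after their values were seen.

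The fits were tested on simulated data: values for the 10081 genes with 200 genes changed. With 1 spread per gene, 159 to 165 changed genes were recovered per genotype comparison and 3.6% to 6.2% of calls were false. Recovery was 44% to 54% for changes of 0.5 on the log2 scale and 96% to 100% for changes of 2. Changes of single genes below 0.5 were not simulated. When the simulated spread followed each day's own, the planned fit at day 0 recovered 167 genes with 320 false calls, while a fit that weights samples by day recovered 136 with 5 false calls; at days 2 to 4 the planned fit gave 0.6% to 1.8% false calls. The weighted fit (limma arrayWeights with day as the group) was therefore added after the data were seen and its counts are printed beside the planned ones; its weights were 0.355, 1.203, 1.696 and 1.382 for days 0, 2, 3 and 4. In 20 simulated runs at day 4 a list shifted by -0.3 passed camera 20 times and other lists 0 times. The spread of each day was simulated as 1 factor per day for all genes, which the weighted fit also assumes. The simulated genes were drawn independently of each other. These runs therefore do not show how often camera passes an unshifted list whose members vary together.

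The libraries of a genotype share mice across days, so the mouse numbers pair the samples by animal. Deviations from the group means of samples of the same mouse had a median correlation across genes of 0.137 in WT (10 of 18 pairs above 0.1) and 0.261 in KO (17 of 18). Absolute depth is unknown. The smallest steps between low FPKM values put the WT day 3 library of mouse 531 at a lower depth than the other libraries of its group (a step ratio of 0.688), while other pairs within groups had ratios from 0.94 to 1.173. Exact zeros can be failed estimates, and such values are given as listed at 0.

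Each result was recomputed with a pseudocount of 0.1, without a filter, with a filter at 5 FPKM, median scaling, only the groups compared, each mouse left out, a block by mouse, neighbouring mouse numbers as a batch, and the estimated correlation. Positions are from GENCODE vM21 for Sting1 and from RefSeq for other genes, both GRCm38, and 99.3% of genes had one. Gm8615 was compared with all GENCODE transcripts by sequence. Figures were drawn with matplotlib 3.10.9.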

Results

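RNA was sequenced from bone-marrow-derived osteoclast precursors of wild-type (WT) mice and of mice lacking STING (KO), the adaptor that signals from cytosolic DNA sensing to type I interferon. Cells of 3 female mice per genotype were sampled before RANKL, the cytokine that drives osteoclast formation, and after 2, 3 and 4 days of RANKL, which gave 24 samples in 8 groups of 3. Each mouse contributed all 4 days, and no mouse is shared between the genotypes (WT mice 480, 529 and 531, KO mice 481, 528 and 532). The deposited table gave FPKM per gene, and 10081 genes were tested. Its summed FPKM ran from 459180 to 734974 per sample. Read depth per sample was not given in the sources used here, so no counting interval is attached to any value. The first principal component held 77.8% of the variance and separated day 0 from the RANKL days, and the second held 12.4% and ordered days 2, 3 and 4. Fold changes below are on the log2(FPKM + 1) scale, which understates changes of genes with low FPKM.

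The targeted gene was examined first. Sting1, listed under its older symbol Tmem173 (GRCm38 chromosome 18, 35733679 to 35740554, minus strand), measured 28.7, 25.4 and 21.3 FPKM in the 3 WT day 0 samples and 5.08, 4.57 and 4.88 FPKM in the 3 KO day 0 samples. It fell by 2.15 on the log2 scale in KO at day 0 (SE 0.121, limma with Benjamini-Hochberg adjustment, adjusted p = 4.24e-10). Sting1 itself decreased over the RANKL days in WT cells. It went from 25.15 ± 3.70 FPKM at day 0 to 4.44 ± 0.919 FPKM at day 4 (SD, n = 3), a log2 change of -2.27 (limma adjusted p = 6.24e-13). WT and KO levels therefore lay close together after RANKL: 6.26 ± 1.04 against 3.49 ± 0.179 FPKM at day 2 (log2 difference -0.68, limma adjusted p = 0.0535). They were 4.43 ± 0.351 against 3.58 ± 0.335 at day 3 (-0.25, limma adjusted p = 1) and 4.44 ± 0.919 against 2.79 ± 0.119 at day 4 (-0.51, limma adjusted p = 1). With samples weighted by day, the day 2 difference passed the threshold (limma adjusted p = 0.0232), as it did without WT mouse 480 (adjusted p = 0.00128). The day 4 difference also passed without that mouse (adjusted p = 0.0123). KO samples thus kept reads on Sting1 at every day, and the mutant allele is not described in the sources used here.

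**Figure D1:**
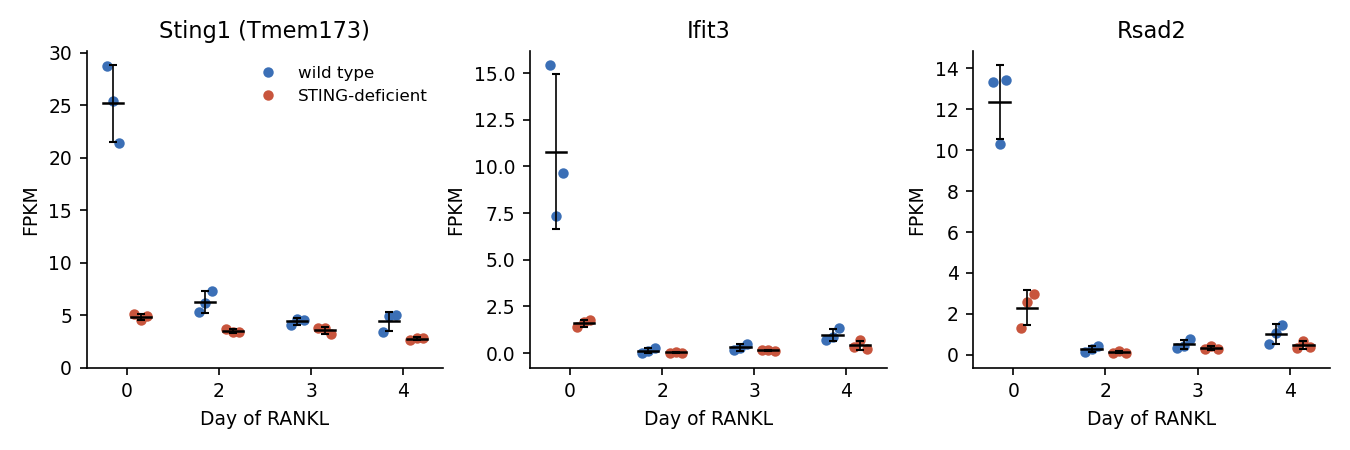
FPKM of Sting1, Ifit3 and Rsad2 (vertical axes) by day of RANKL (horizontal axes) in WT and KO cultures, with 1 point per mouse, a line at the mean and bars of 1 SD (n = 3). At day 0 the 3 WT samples lie above the 3 KO samples for each gene, between 21.3 and 28.7 FPKM against 4.57 to 5.08 FPKM for Sting1.

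The comparison of the genotypes at day 0 asks how STING shapes the precursors before RANKL. Interferon-stimulated genes were lower in KO cells: 64 of the 65 tested members of the list had a negative log2 difference. The median was -0.73. The antiviral genes Ifit3 and Rsad2 fell from 10.8 ± 4.17 to 1.60 ± 0.197 FPKM and from 12.4 ± 1.80 to 2.29 ± 0.857 FPKM (SD, n = 3), log2 changes of -2.13 and -2.05 (limma adjusted p = 4.94e-07 and 8.84e-07). Isg15, a ubiquitin-like modifier, changed by -1.91, Ifit1 by -1.91, the chemokine Cxcl10 by -1.87, Usp18, which removes Isg15 from its targets, by -1.66, and Oasl1 by -1.47 (limma adjusted p between 1.3e-05 and 0.00341). The chemokine gene Ccl5, from the list of inflammatory cytokines and chemokines, fell from 7.27 ± 2.09 to 1.55 ± 0.768 FPKM (limma adjusted p = 0.00118). With samples weighted by day, Isg15, Cxcl10 and Ccl5 did not pass (limma adjusted p = 0.275 for Isg15 and 0.36 for Ccl5). That fit applies 1 weight per day to all genes, and single genes can depart from it. Cxcl10 in WT measured 10.3 ± 1.52 FPKM at day 0 and 4.93 ± 2.70 FPKM at day 4. In KO it measured 2.10 ± 0.479 FPKM at day 0. Of the interferon-stimulated list 25 members fell with adjustment over all genes tested, and 59 fell when adjusted over the list alone. The list passed camera, limma's test of a list against all other genes, with a preset correlation (adjusted p = 2.11e-65) and with an estimated correlation (adjusted p = 0.029). Reads of near-identical paralogs (Ifit3 with I830012O16Rik, and the Oas family) could be split between them, so their single values are uncertain.

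Over all genes tested, 38 of 10081 differed between the genotypes at day 0, of which 35 fell and 3 rose in KO. Of the 35, 25 belonged to the interferon-stimulated list. The 3 that rose were Gm8615, a pseudogene described below, Pcbp3 (1.76 ± 0.0383 to 2.58 ± 0.259 FPKM) and Fam65b (1.44 ± 0.083 to 2.13 ± 0.311 FPKM). Samples varied more at day 0 than later, with a median SD of 0.187 in WT and 0.177 in KO on the log2 scale against 0.078 to 0.122 at the other days. With samples weighted by day, 10 of the 38 passed: Gm8615, Sting1, Ifit3, Rsad2, I830012O16Rik, Mx1, Mx2, Oasl1, Usp18 and Ifit1. In simulated data with the spread of each day, 320 false calls arose at day 0 with equal weights and 5 with weights by day. In the weighted fit 8 members of the interferon-stimulated list fell, and 36 when adjusted over the list alone. The count was 14 with a pseudocount of 0.1, 5 in a fit on the day 0 samples alone, 19 without KO mouse 481 and 84 without WT mouse 529. The balance of directions moved too: 25 rose and 59 fell without WT mouse 529, 13 rose and 35 fell without KO mouse 528, and 9 rose and 22 fell without WT mouse 480. Without mice 480 and 481, 19 rose and 20 fell, and 17 of these 39 were among the 38.

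Other gene groups at day 0 moved less. Cytosolic DNA sensing genes had a median of -0.13 (camera adjusted p = 0.0142, adjusted p = 0.452 with an estimated correlation). Of its members 2 of 19 fell (3 when adjusted over the list alone): Zbp1 by 1.51 on the log2 scale and Trex1, a DNA exonuclease, by 0.74 (limma adjusted p = 0.0144 and 0.0294). Neither Zbp1 nor Trex1 passed with samples weighted by day (limma adjusted p = 0.657 for Trex1). Lysosome and proton pump genes had a median of -0.17 (camera adjusted p = 4.1e-06, adjusted p = 0.452 with an estimated correlation), and 1 of 35 fell when adjusted over the list alone. Npc2, a lysosomal cholesterol carrier, measured 542 ± 83.1 FPKM in WT and 409 ± 41.5 FPKM in KO (limma adjusted p = 0.137). Oxidative phosphorylation genes had a median of -0.12 (camera adjusted p = 0.0142, adjusted p = 0.773 with an estimated correlation), and the call was lost without WT mouse 531 (adjusted p = 0.632) or KO mouse 532 (adjusted p = 0.725). Cell cycle genes were higher in KO, with 45 of 47 members positive and a median of 0.27 (camera adjusted p = 9.35e-14, adjusted p = 0.452 with an estimated correlation). Mki67 measured 17.5 ± 2.18 FPKM in WT and 28.0 ± 6.99 FPKM in KO. That median was 0.06 without WT mouse 480 (camera adjusted p = 0.143). B cell markers were also higher in KO (median 0.63, camera adjusted p = 0.0117, adjusted p = 0.696 with an estimated correlation), with Cd79a at 24.3 FPKM in WT mouse 480 and 34.1 FPKM in KO mouse 481 against 4.66 to 10.6 FPKM in the other 4 day 0 samples. Without KO mouse 481 the adjusted p was 0.569. Without WT mouse 480 or KO mouse 528 the cytosolic DNA sensing call was lost (adjusted p = 0.241 and 0.172), and without WT mouse 529 or 531 so was that of the B cell markers (adjusted p = 0.532 and 0.15). Neutrophil markers were high in all day 0 samples, S100a8 at 1662 to 4655 FPKM, and did not pass between the genotypes (median 0.10, camera adjusted p = 0.109). The osteoclast effector list had a median of -0.03 at day 0 (camera adjusted p = 0.688), with Ctsk, the collagen-degrading protease of osteoclasts, at 30.8 ± 13.1 FPKM in WT and 23.2 ± 22.6 FPKM in KO. Without KO mouse 481 the list had a median of -0.12 and passed (adjusted p = 0.00279).

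After RANKL the interferon-stimulated genes stayed lower in KO as a list, by less than at day 0. The median log2 difference was -0.13 at day 2, -0.16 at day 3 and -0.28 at day 4, with 59, 59 and 60 of 65 members negative (camera adjusted p = 4.67e-09, 4.53e-10 and 1.12e-49). With an estimated correlation none of the 3 passed (adjusted p = 0.627, 0.903 and 0.0855). The means of the list overlapped between the genotypes on these days. WT mouse 480 lay below KO mouse 528, at 2.11, 2.09 and 2.38 against 2.16, 2.19 and 2.55. WT mouse 480 was also low for macrophage genes at day 4 (4.53 against 5.17 and 5.09 in the other WT mice). Leaving out single mice kept the calls and moved the median to -0.06 at day 2 (without KO 481), to between -0.26 (without WT 480) and -0.09 (without KO 481 or WT 531, and -0.11 without WT 529) at day 3, and to -0.46 (without WT 480) and -0.13 (without WT 531) at day 4. No single member passed on any of these days, either over all genes or adjusted over the list alone, by limma with equal weights. At unadjusted p below 0.05 the whole table held 65, 78 and 81 genes at days 2, 3 and 4. Each is fewer than a share of 0.05 of the 10081 genes tested, which p-values would give without any difference. The fit with equal weights was thus strict on these days, and a lack of calls does not show a lack of difference. With samples weighted by day, 14 members fell at day 4 when adjusted over the list alone. At day 4 Oasl2 measured 3.09 ± 1.98 FPKM in WT and 0.974 ± 0.390 FPKM in KO, Usp18 1.57 ± 0.723 and 0.696 ± 0.249 FPKM, Oas3 3.52 ± 1.46 and 1.86 ± 0.354 FPKM, and Cmpk2 1.25 ± 0.549 and 0.518 ± 0.271 FPKM (SD, n = 3). Ccl5 measured 1.92 ± 1.02 FPKM in WT and 0.152 ± 0.174 FPKM in KO at day 2 (limma adjusted p = 0.154), and passed with a pseudocount of 0.1 (adjusted p = 0.0125) and without WT mouse 480 (adjusted p = 0.00218).

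**Figure D2:**
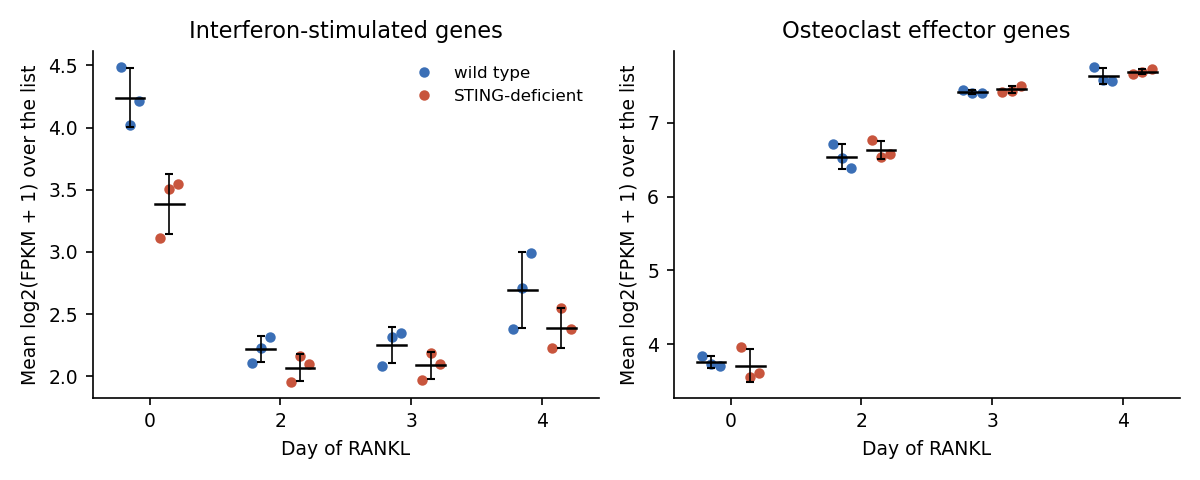
Mean log2(FPKM + 1) over the 65 interferon-stimulated genes and the 40 osteoclast effector genes (vertical axes) by day of RANKL (horizontal axes), with 1 point per mouse, a line at the mean and bars of 1 SD (n = 3). The interferon-stimulated mean lies between 4.02 and 4.49 in WT and 3.11 and 3.54 in KO at day 0, and the osteoclast effector means of the genotypes lie close together on each day.

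The series title places STING as a restraint on osteoclast differentiation, so the osteoclast effector genes were compared on each RANKL day. At day 2 they were slightly higher in KO, with 36 of 40 positive and a median log2 difference of 0.11 (camera adjusted p = 1.66e-05, adjusted p = 0.51 with an estimated correlation). The call was lost without WT mouse 531 (median 0.01, adjusted p = 0.797) and without KO mouse 481 (median 0.03, adjusted p = 0.35). At day 3 the median was 0.05 with 27 of 40 positive (camera adjusted p = 0.4), and at day 4 it was 0.06 with 34 of 40 positive (camera adjusted p = 0.0916). The day 4 list passed without WT mouse 480 (median 0.14, adjusted p = 0.00102), without KO mouse 481 (median 0.08, adjusted p = 0.00325) and in a fit on the day 4 samples alone (adjusted p = 0.0358). No member passed on any day, over all genes or adjusted over the list alone. Since the fit with equal weights was strict on the RANKL days, this does not show equal levels. At day 4 Dcstamp, required for fusion of osteoclast precursors, measured 433.5 ± 51.1 FPKM in WT and 492 ± 8.42 FPKM in KO, Ckb 5811 ± 673 and 6434 ± 212 FPKM, and the carbonic anhydrase gene Car2 210.4 ± 8.95 and 232 ± 27.3 FPKM (SD, n = 3).

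Mitochondrial and lysosomal genes were slightly higher in KO at day 3. Of the 39 oxidative phosphorylation genes 38 were positive, with a median of 0.11 (camera adjusted p = 8.52e-11, adjusted p = 0.468 with an estimated correlation). Of the 35 lysosome and proton pump genes 29 were positive, with a median of 0.09 (camera adjusted p = 5.58e-06, adjusted p = 0.468 with an estimated correlation). Uqcrc1 measured 411 ± 31.8 FPKM in WT and 457 ± 20.5 FPKM in KO at day 3. Cell cycle genes were lower in KO at days 2 and 3, with 46 of 47 negative on each day and medians of -0.10 and -0.09 (camera adjusted p = 6.97e-06 and 3.44e-06, adjusted p = 0.627 and 0.976 with an estimated correlation). The day 3 call was lost without KO mouse 532 (adjusted p = 0.0832), and the day 2 call without WT mouse 529 or 531 or KO mouse 481 (adjusted p = 0.12, 0.255 and 0.571). At day 2 the inflammatory cytokine (median -0.09), immediate early (-0.04), oxidative phosphorylation (0.04), neutrophil (0.10) and chromosome 18 neighbour (0.003) lists also passed (camera adjusted p between 0.0102 and 0.0324, adjusted p of at least 0.214 with an estimated correlation). Each lost its call without WT mouse 529 (adjusted p of up to 0.595). At day 4 the macrophage (median -0.11), oxidative phosphorylation (0.06), lysosome (0.05) and neutrophil (0.18) lists passed (camera adjusted p = 0.0428, 0.000341, 0.0499 and 0.0428, adjusted p = 0.868 each with an estimated correlation). The first 3 lost their calls without WT mouse 529 (adjusted p = 0.293, 0.936 and 0.52) and the neutrophil list without WT mouse 531 (adjusted p = 0.973). Members with the smallest p in the macrophage list lay the other way at day 4: Ccr2 measured 1.37 ± 0.286 FPKM in WT and 1.98 ± 0.250 FPKM in KO, and Marco 1.45 ± 0.436 and 2.71 ± 1.03 FPKM (limma adjusted p = 1 each).

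At the level of single genes, 1 gene differed between the genotypes on each RANKL day, and it was the same gene, Gm8615. Outside the rule for named genes and chosen after its values were seen, this pseudogene (chromosome 5, 149154128 to 149156192) was listed at 0 FPKM in the 3 WT day 0 samples and at 6.1, 7.05 and 4.84 FPKM in the 3 KO day 0 samples. At days 2, 3 and 4 it measured at most 0.0495 FPKM in WT and 1.84 ± 0.128, 2.22 ± 0.113 and 2.95 ± 0.206 FPKM in KO (log2 differences 1.45, 1.66 and 1.92, limma adjusted p = 2.55e-09, 1.8e-10 and 1.04e-11). Its 771-base transcript matched 1 other gene, Gnpda1, at 99.07% over 753 bases, so reads can pass between them and both values are uncertain. Gnpda1 lies on chromosome 18 (38327537 to 38338993), near Sting1. With samples weighted by day, further genes passed: Stard4, a sterol transfer protein gene, was higher in KO at days 2, 3 and 4 (7.44 ± 0.804 against 4.28 ± 0.394 FPKM, 8.36 ± 0.420 against 4.87 ± 0.268 FPKM, and 8.89 ± 0.887 against 5.16 ± 0.499 FPKM; limma adjusted p = 0.00309, 0.000223 and 0.000913). Arap3, a GTPase regulator gene, was higher at day 4 (28.4 ± 2.67 against 18.4 ± 1.30 FPKM, limma adjusted p = 0.0475). With equal weights the adjusted p of Stard4 was 0.0535, 0.069 and 0.0585 and that of Arap3 at day 4 was 1. Both were chosen after their values were seen, and both lie on chromosome 18 (33199138 to 33213862 and 37972623 to 37999531).

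**Figure D3:**
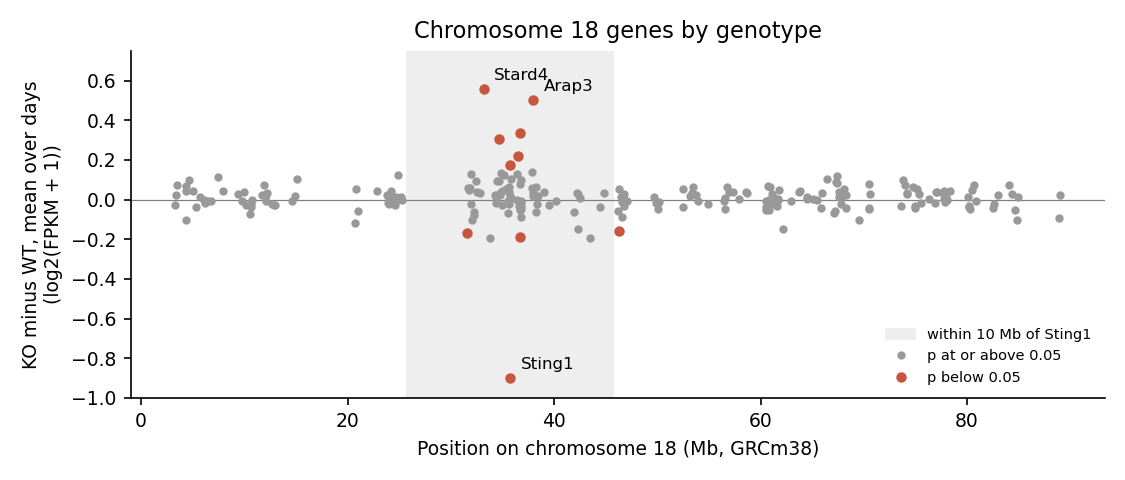
Mean log2(FPKM + 1) difference of KO minus WT over the 4 days (vertical axis) for each tested gene on chromosome 18 by its position in GRCm38 (horizontal axis, Mb), with genes at p below 0.05 by limma on 1 mean per mouse in red. Sting1 lies lowest at -0.90, and Stard4 (0.56) and Arap3 (0.50) lie highest, inside the shaded window of 10 Mb to each side of Sting1.

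The RANKL course was compared with day 0 within each genotype. Day 0 cells had the 40 ng/mL mCSF of the expansion and no RANKL, and later cells had RANKL with 20 ng/mL mCSF. No culture without RANKL was sampled at days 2 to 4. RANKL, the lower mCSF and time in culture can therefore not be told apart in these changes. In WT cells the osteoclast effector list rose by a median log2 of 2.22, 3.97 and 4.08 at days 2, 3 and 4, with 33, 35 and 33 of 40 members rising (camera adjusted p = 4.83e-09, 1.07e-10 and 1.3e-10; adjusted p = 0.169, 0.184 and 0.148 with an estimated correlation). Acp5, which encodes tartrate-resistant acid phosphatase, went from 22.3 ± 3.52 FPKM at day 0 to 19070 ± 774 FPKM at day 4, Ctsk from 30.8 ± 13.1 to 12070 ± 1240 FPKM, and Mmp9 from 19.2 ± 4.13 to 10470 ± 1630 FPKM (SD, n = 3). The other genes with the largest WT rises at day 4 were Mt3, Oscar, Akr1c18, Nhedc2 and Dcstamp, with log2 changes from 7.17 to 9.11 (limma adjusted p between 1.89e-19 and 7.43e-15). RANK and NF-kB signalling genes rose, with 20 of 23 members and a median of 1.30 at day 4 (camera adjusted p = 1.32e-05, adjusted p = 0.183 with an estimated correlation), among them the RANK gene Tnfrsf11a (10.5 ± 0.883 to 43.8 ± 4.35 FPKM). Cell fusion and adhesion genes rose in 12 and fell in 6 of 18 members, with a median of 1.2 (camera adjusted p = 0.0189, adjusted p = 0.22 with an estimated correlation). Oxidative phosphorylation genes rose in 30 of 39 members with a median of 0.73 (camera adjusted p = 3.68e-06, adjusted p = 0.309 with an estimated correlation), led by Uqcrc2 and by Ppargc1b, a coactivator of mitochondrial biogenesis (0.994 ± 0.193 to 14.9 ± 1.01 FPKM).

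**Figure D4:**
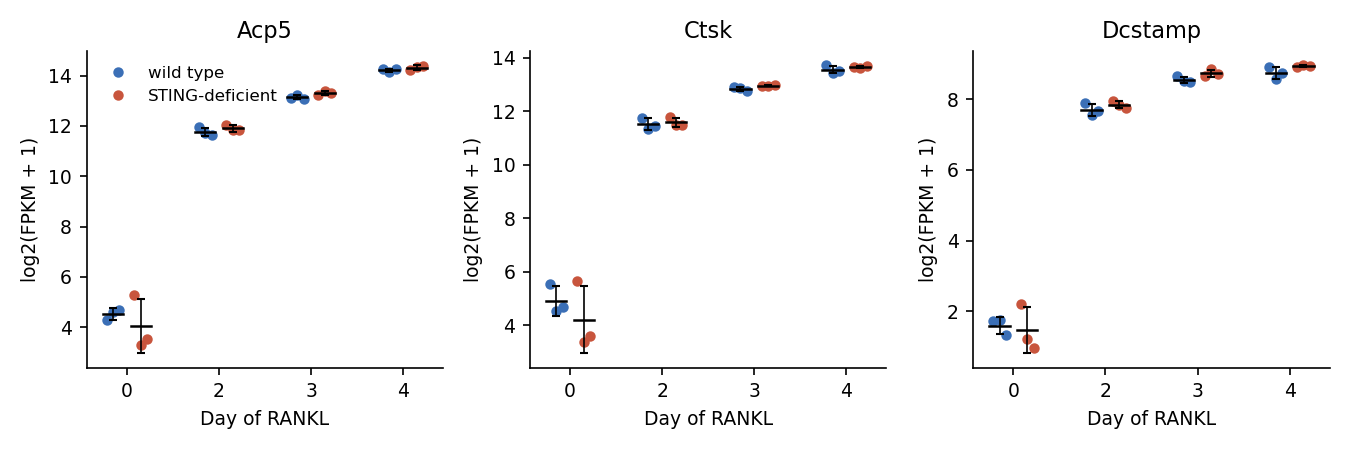
Log2(FPKM + 1) of Acp5, Ctsk and Dcstamp (vertical axes) by day of RANKL (horizontal axes) in WT and KO cultures, with 1 point per mouse, a line at the mean and bars of 1 SD (n = 3). Each gene rises from day 0 to day 2 in both genotypes, and at day 4 the WT and KO points lie together.

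Precursor, inflammatory and proliferation genes fell over the same days in WT cells. The macrophage list had a median of -1.56 at day 4 with 24 of 29 members falling (camera adjusted p = 5.42e-05, adjusted p = 0.289 with an estimated correlation), including the monocyte genes Ccr2 (34.5 ± 6.46 to 1.37 ± 0.286 FPKM) and Ly6c2 (97.9 ± 29.4 to 1.02 ± 0.565 FPKM). Inflammatory cytokine genes had a median of -2.30 with 14 of 17 falling (camera adjusted p = 0.00105, adjusted p = 0.148 with an estimated correlation). Ccl3 and Cxcl2 fell, while Lif rose from 0.0836 ± 0.0157 to 8.77 ± 0.699 FPKM. Interferon-stimulated genes fell in 54 of 65 members with a median of -1.58 (camera adjusted p = 9.6e-08, adjusted p = 0.339 with an estimated correlation), for example Bst2 from 457 ± 102 to 53.7 ± 11.6 FPKM. Cytosolic DNA sensing genes fell in 15 of 19 (median -0.94, camera adjusted p = 0.00421, adjusted p = 0.226 with an estimated correlation). Cell cycle genes did not pass at day 2 (median 0.16, camera adjusted p = 0.581) and had medians of -0.59 at day 3 and -1.27 at day 4, when 45 of 47 fell (camera adjusted p = 0.000819 and 8.46e-08, adjusted p = 0.533 and 0.339 with an estimated correlation). Cholesterol biosynthesis genes fell in 18 of 21 (median -1.34, camera adjusted p = 3.68e-06, adjusted p = 0.148 with an estimated correlation), for example the farnesyl diphosphate synthase gene Fdps from 301.5 ± 21.2 to 33.5 ± 1.40 FPKM. The integrated stress response, immediate early and class II antigen presentation lists had medians of -1.0, -1.49 and -1.14 (camera adjusted p = 0.00451, 0.0041 and 0.00643, adjusted p = 0.279, 0.148 and 0.28 with an estimated correlation). The lysosome list had a median of 0.53 with 24 of 35 rising and 10 falling (camera adjusted p = 0.0426, adjusted p = 0.434 with an estimated correlation). It lost its call without WT mouse 531 (adjusted p = 0.0638).

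Markers of other blood cells fell over the RANKL days as well. How much of the other changes from day 0 goes with the loss of these cells was not measured. In WT cells all 13 neutrophil markers fell at day 4 with a median of -5.70 (camera adjusted p = 1.14e-06, adjusted p = 0.148 with an estimated correlation), and Camp, S100a9, S100a8 and Retnlg were among the 8 genes with the largest falls, beside Ccl7, Ccl2, Gdf15 and Rgs1. S100a9 went from 4806 ± 2610 to 45.6 ± 23.0 FPKM. All 7 B cell markers (median -1.62) and all 9 megakaryocyte, mast cell and basophil markers (median -2.15) fell too (camera adjusted p = 0.0162 and 0.000693, adjusted p = 0.379 and 0.22 with an estimated correlation). In total 8198, 8598 and 8612 of 10081 genes passed at days 2, 3 and 4 in WT, with 4120 rising and 4492 falling at day 4. The table was preselected by a rule that is not given. Such counts, in WT and in KO, therefore do not give the share of all expressed genes that changed. Camera likewise compares each list only with other genes of that table.

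KO cells went through the same comparison with 8015, 8348 and 8448 genes past the threshold at days 2, 3 and 4, and 4104 rising and 4344 falling at day 4. Osteoclast effector genes had medians of 2.52, 4.10 and 4.27 with 33, 35 and 34 of 40 rising (camera adjusted p = 8.51e-10, 3.13e-11 and 6.39e-11, adjusted p = 0.135, 0.141 and 0.126 with an estimated correlation). Acp5 went from 18.95 ± 16 FPKM at day 0 to 20510 ± 1360 FPKM at day 4, Ctsk from 23.2 ± 22.6 to 12910 ± 346 FPKM, and the other largest rises were again Mt3, Mmp9, Oscar, Dcstamp, Nhedc2 and Akr1c18. Interferon-stimulated genes fell in 51 of 65 members with a median of -1.01 at day 4 (camera adjusted p = 8.73e-05, adjusted p = 0.439 with an estimated correlation), while Gbp7 rose from 0.644 ± 0.263 to 5.39 ± 0.782 FPKM. Cell cycle genes fell in 46 of 47 (median -1.60) and oxidative phosphorylation genes rose in 36 of 39 (median 0.90; camera adjusted p = 2.01e-10 and 8.63e-08, adjusted p = 0.242 and 0.218 with an estimated correlation). Lysosome genes had a median of 0.90 with 24 of 35 rising and 10 falling (camera adjusted p = 0.00869, adjusted p = 0.313 with an estimated correlation), and neutrophil markers fell in 13 of 13 (median -5.51, camera adjusted p = 4.51e-07, adjusted p = 0.126 with an estimated correlation). In each genotype 17 or 18 of 23 lists passed at day 4, and none did with an estimated correlation.

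The interaction asks whether the RANKL course itself differed between the genotypes. By limma's F test 7 genes passed: Sting1 and Gm8615 (adjusted p = 1.3e-05 each), the interferon-stimulated genes Ifit3, Rsad2, Mx1 and Usp18 (adjusted p = 0.000704, 0.00149, 0.0209 and 0.0366) and I830012O16Rik, a paralog of Ifit3 named after its value was seen (adjusted p = 0.0379). For the interferon-stimulated genes the log2 gap between WT and KO was wider at day 0 than after RANKL. Ifit3 measured 0.961 ± 0.338 FPKM in WT and 0.418 ± 0.231 FPKM in KO at day 4, Rsad2 1.01 ± 0.468 and 0.458 ± 0.193 FPKM, and Usp18 1.57 ± 0.723 and 0.696 ± 0.249 FPKM. Mx1 measured 3.15 ± 0.812 against 1.11 ± 0.333 FPKM at day 0 and 0.183 ± 0.0213 against 0.153 ± 0.102 FPKM at day 4 (SD, n = 3). None of the osteoclast effector genes passed. The members with the smallest p, Fosl1, Atp6v1c1, Snx10 and Mitf, had an adjusted p of 1. Over all 10081 genes the F test gave 213 at an unadjusted p below 0.05, fewer than a share of 0.05. The lack of calls thus does not show equal courses. Weighted by day, 3 of the genes passed (Gm8615, Sting1 and Ifit3), and 2 genes passed with a pseudocount of 0.1, where Ifit3, Rsad2, Mx1 and Usp18 had an adjusted p of 1. Without WT mouse 529 the count was 4. With a block by mouse Mx1 and I830012O16Rik no longer passed (adjusted p = 0.054 and 0.124), and Oasl1, an interferon-stimulated gene, did (adjusted p = 0.00802).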

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

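The tests of other cell types at day 0 and of a single library were chosen only after the result was seen, as were the weighting by day, the splits with that weighting and the fit without mice 480 and 481. The 7 genes and the lists of the next paragraph drew attention because the effect of the genotype differed between days, by a test of the interaction, and the genes near Sting1 by their mean difference over the days.

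The RANKL course differed between the genotypes for 7 genes by limma's F test: Sting1 (Tmem173, adjusted p = 1.3e-05), Gm8615 (1.3e-05), Ifit3 (0.000704), Rsad2 (0.00149), Mx1 (0.0209), Usp18 (0.0366) and I830012O16Rik (0.0379). As a list, the interferon-stimulated genes lost less from day 0 in KO than in WT, by a median log2 of 0.66, 0.62 and 0.45 at days 2, 3 and 4 (0.657, 0.617 and 0.446). Cell cycle genes went the other way (-0.366, -0.37 and -0.247), as did B cell markers (-0.606, -0.643 and -0.617). Both depended on single mice: without WT mouse 480 the cell cycle difference was -0.229, -0.176 and -0.017 at days 2, 3 and 4 (adjusted p = 1e-08, 0.000301 and 0.307), and the B cell markers lost their calls without KO mouse 481 (-0.133, -0.128 and -0.143) and, on each of the 3 days, without WT mouse 529 or 531 (adjusted p from 0.182 to 0.863). Oxidative phosphorylation genes (0.121, 0.235 and 0.159), lysosome genes (0.149, 0.235 and 0.176) and, at day 2, osteoclast effector genes (0.123) lay higher in their change in KO. For lysosome genes at day 2 this was a smaller loss, with medians of -0.37 in WT and -0.20 in KO. By camera with a preset correlation 6, 5 and 5 lists passed at days 2, 3 and 4, and with an estimated correlation 0 passed (lowest adjusted p 0.0859, 0.225 and 0.302). Of the 10 splits of the 6 mice 2, the real one included, gave at least 7 genes. The real interaction gave 7 and the highest other split 177. With 10 splits no share under 0.05 can be had.

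The first pattern is that interferon-stimulated genes fell further in KO at day 0 than after RANKL, when these genes had themselves fallen in WT. A pseudocount of 1 compresses low values, and with a pseudocount of 0.1 the list still differed between the days, with a smallest median difference of 0.434. For the list as a whole this argues against compression as the whole cause. Members below 0.1 FPKM after RANKL are still compressed, such as Ifit3 and Mx1 in KO at day 2 (means of 0.0415 and 0.00995 FPKM). For such members the test cannot decide. With 0.1, Ifit3, Rsad2, Mx1 and Usp18 no longer passed the interaction (adjusted p = 1 each), with larger standard errors. The differences of Ifit3 and Rsad2 stayed near their size at days 2, 3 and 4, while Usp18 went from 1.42 to 0.97 at day 2 and from 1.46 to 1.19 at day 3, and Mx1 from 0.95 to 1.29 at day 3. At day 4 Ifit3 had 1.66 (SE 0.254) with 1 and 1.54 (SE 0.587) with 0.1, Rsad2 1.60 (0.257) and 1.49 (0.532), Mx1 0.93 (0.161) and 1.21 (0.433), and Usp18 1.08 (0.249) and 0.85 (0.442). For other cell types in the day 0 cultures, 0 of 4 marker lists were lower in KO. The mean differences of the neutrophil, B cell, dendritic cell and megakaryocyte lists were 0.15, 0.48, 0.01 and 0.10, against a fall of those cells. The B cell list passed camera as higher (adjusted p = 0.0117). That call was lost with an estimated correlation, without KO mouse 481 (adjusted p = 0.569) and without WT mouse 529 or 531 (adjusted p = 0.532 and 0.15). With 3 mice per genotype the lower 95% limits (-0.86, -1.22, -0.83 and -0.80) still reach the interferon-stimulated median of -0.73, so for the list as a whole such a fall is not excluded and cannot be told apart from an effect of STING before RANKL.

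The second pattern is that genes near Sting1 differed between the genotypes. The neighbours Stard4 and Arap3 were higher in KO, and leaving out the 6 neighbours noticed first, 4 of 66 other genes within 10 Mb had p under 0.05 against 152 of 9941 elsewhere (odds ratio 4.153, 95% interval 1.084 to 11.397, Fisher exact p = 0.0194). A chromosome segment of another strain carried along with the Sting1 allele could give this, its extent was not measured, and effects of STING itself on these genes remain open. Reads of Gnpda1, the only gene similar to Gm8615 and within the same 10 Mb, could be counted for the pseudogene. The Gnpda1 loss came to a median of 13.7% of the Gm8615 gain with the RefSeq span of Gm8615 and 36.7% with its 771-base transcript, with standard errors above 100% on every day. At day 2 Gnpda1 was not lower in KO (27.96 against 27.52 FPKM, a share of -27.5% or -73.7%), so the source of the Gm8615 reads cannot be told apart.

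The third pattern is the higher cell cycle list in KO at day 0. Its median of 0.267 was 0.064 without WT mouse 480 and 0.058 without mice 480 and 481, whose libraries deviate together (correlation across genes 0.547 at day 0). At day 0 WT mice 529 and 531 also deviated with a KO mouse (highest correlations 0.612 and 0.562). It was not the KO mouse of the neighbouring number (-0.099 and -0.292). For WT mice 529 and 531 the batch by neighbouring numbers thus did not cover what cultures share across genotypes. The mean of the list was 4.39 in WT mouse 480, 5.03 and 5.05 in the other WT mice and 5.06, 5.08 and 5.14 in KO mice 481, 528 and 532. Most of the difference thus lay in 1 library, and KO mouse 481 was not low with it. Whether the remainder of 0.064 or less is due to the genotype cannot be told apart from the spread of 2 or 3 mice. At day 0 the split that put KO mice 481 and 532 with WT mouse 480 gave 2364 genes against 38 for the genotypes, and 6 of 10 splits, the real one included, gave at least as many. With samples weighted by day that split gave 233 genes against 10, and 4 of 10 splits gave at least as many. This points to a structure of the day 0 samples other than genotype, by a smaller count with the weights.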

How the results depend on the processing

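The weighting by day, the fit without mice 480 and 481, the fit on days 2 to 4 and the fit without the WT day 3 library of mouse 531 were chosen only after the result was seen. Over all alternatives 120 of 136 values of the interferon-stimulated and osteoclast effector lists, 126 of 155 counts, 58 of 64 values of Sting1, 5773 of 5866 values of named genes and 961 of 1122 values of other lists kept their direction and side of the threshold, or for counts stayed within 1.5 times. The interferon-stimulated list kept both under every alternative but the estimated correlation, with medians from -0.885 to -0.446 at day 0, -0.25 to -0.059 at day 2, -0.255 to -0.086 at day 3 and -0.464 to -0.132 at day 4. The cause of the changes below was not tested, except that fits on fewer samples have less information on the spread.

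Counts of genes between the genotypes moved as follows. A pseudocount of 0.1 gave 14, 4 and 2 genes at days 0, 2 and 4 and 2 for the interaction. A filter at 5 FPKM gave 3 genes at day 2, 2 at day 4 and 4 for the interaction, and no filter gave 3 at day 4. Median scaling gave 2 genes at day 2 and 2 at day 3. Only the groups compared gave 5 genes at day 0 and 3 at day 3; for the interaction that setting equals the full fit and gives no other value. Weighting by day gave 10, 3, 2 and 3 genes at days 0, 2, 3 and 4 and 3 for the interaction. Without mice 480 and 481 there were 2 genes at day 2, the fit on days 2 to 4 gave 3, 2 and 3 genes at days 2, 3 and 4, and without the WT day 3 library of mouse 531 there were 2 at day 3. Leaving out each mouse gave 19 (without KO 481) to 84 (without WT 529) genes at day 0, 1 to 3 at day 2, 1 to 2 at day 3, 1 to 2 at day 4 (the highest each without WT 480, at day 3 also without WT 531) and 4 (without WT 529) to 6 for the interaction.

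With an estimated correlation the interferon-stimulated list no longer passed at days 2, 3 and 4 (medians -0.125, -0.164 and -0.283, adjusted p = 0.627, 0.903 and 0.0855), nor did the osteoclast effector list at day 2 (0.113, adjusted p = 0.51). Leaving out each mouse moved the osteoclast effector median from -0.122 (without KO 481) to 0.028 (without KO 528) at day 0, where it was also reversed without KO 532 (0.01), from 0.008 (without WT 531) to 0.203 (without WT 480) at day 2 and from 0.019 (without WT 531) to 0.136 (without WT 480) at day 4. Without mice 480 and 481 that list passed at days 0, 3 and 4 (-0.08, 0.073 and 0.163), and at day 4 also with only the groups compared (0.061) and on days 2 to 4 (0.061). Sting1 at day 2 passed with a pseudocount of 0.1 (-0.811), a filter at 5 FPKM (-0.682), weighting by day (-0.682) and without mice 480 and 481 (-0.815), and leaving out each mouse its value ran from -0.782 (without WT 480) to -0.576 at day 2 and from -0.657 (without WT 480, where it passed) to -0.428 at day 4. Directions reversed without WT 529 for oxidative phosphorylation at day 2 (-0.035) and day 4 (-0.008, up to 0.109 without WT 480), for macrophage genes at day 4 (0.003, down to -0.323 without WT 480) and for the chromosome 18 neighbours at day 2 (-0.013, up to 0.018 without WT 531), the last also without KO 532 (-0.001).

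A replicate block by mouse gave 37, 1, 1 and 1 genes between the genotypes at days 0, 2, 3 and 4. By limma on 1 mean per mouse over the days, 2 of 10081 genes differed between the genotypes. They were Gm8615 and Sting1 (limma adjusted p = 1.33e-05 and 0.00312). Ifit3 and Rsad2 did not pass there (limma adjusted p = 0.0521 and 0.243). A fixed block gave 8456, 8756 and 8783 genes over time in WT, 8283, 8561 and 8629 in KO and 6 for the interaction, 5 of them among the 7, without Mx1 and I830012O16Rik and with Oasl1. Absolute depth is unknown, so what depth limits was not assessed.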

Other observations

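The comparison of day 4 with day 3 was chosen only after the data were seen, and so were the genes named from it. From day 3 to day 4 macrophage genes rose again in both genotypes, with a median log2 change of 0.67 in WT (22 of 29 rose, camera adjusted p = 2.49e-12, adjusted p = 0.235 with an estimated correlation) and 0.69 in KO (19 of 29 rose, adjusted p = 2.1e-12 and 0.223). The mannose receptor gene Mrc1 rose by 1.84 in WT and 1.97 in KO (limma adjusted p = 0.000959 and 0.000661), and the class II antigen presentation gene H2-Aa by 1.71 and 1.60 (limma adjusted p = 0.00153 and 0.00318). Interferon-stimulated genes rose too, by a median of 0.50 in WT (26 of 65 rose, 33 when adjusted over the list alone; camera adjusted p = 3.74e-08, adjusted p = 0.607 with an estimated correlation) and 0.33 in KO (7 of 65 rose, 3 when adjusted over the list alone; adjusted p = 0.000402 and 0.681), among them Irf7, which drives interferon genes (1.09 and 0.91, limma adjusted p = 0.00561 and 0.02). Lysosome genes rose by 0.34 and 0.32 (camera adjusted p = 3.87e-13 and 6.16e-12, adjusted p = 0.0957 and 0.142 with an estimated correlation), and cell cycle genes fell by 0.58 and 0.44 (camera adjusted p = 1.05e-17 and 9.29e-14, adjusted p = 0.384 and 0.578 with an estimated correlation). In all 2195 genes passed in WT and 1809 in KO, and by limma 0 genes differed in this step between the genotypes (32 at an unadjusted p under 0.05). The 32 are fewer than a share of 0.05 of the genes tested, so the lack of calls does not show equal steps. As lists, the interferon-stimulated genes (median difference -0.12, camera adjusted p = 8.05e-09), cell cycle genes (0.125, 8.56e-07), oxidative phosphorylation genes (-0.04, 0.00763) and lysosome genes (-0.03, 0.0448) passed for the difference of KO minus WT, each with an adjusted p = 0.958 with an estimated correlation.

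The other counts were set beside splits of the same samples. At days 2, 3 and 4 the genotypes gave 1 gene each, and the highest of the other splits gave 0, 1 and 0, so that 1, 2 and 1 of 10 splits, the real one included, gave as many genes. For the RANKL days against day 0, 1 of 10 splits, the real one, gave as many genes in each genotype and on each day, with the highest other at 0 on days 2 and 3 and 1 on day 4. Every other split there puts day 0 and RANKL samples in both groups, which widens the spread within them. Few genes follow from that alone, so these splits draw no conclusion on the RANKL days. In each comparison 10 splits are too few for a share under 0.05.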
